A study of Arabidopsis thaliana with 22 samples.

How the data were processed

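The samples were roots of 11-day-old Arabidopsis plants of the wild type Ws and of the proscoop12 mutant, taken as meristematic-elongation zone or differentiation zone, after water or 100 nM SCOOP12, per the labels. Plants grew in short days: light lasted 8 h at 22 °C, darkness 16 h at 21 °C, and relative humidity was 70%, per the labels. Stranded mRNA libraries were made from total RNA and sequenced as pairs of 100 nt reads, per the labels' protocols. The authors quantified reads with Salmon, and the values used here are its estimated counts per transcript, per the file headers. The same files give TPM, which sum to 1000000 over the listed transcripts, per the file headers; TPM was used only to check the files. Salmon's version, its library-type setting, the genome build, the annotation and the strand that was counted are not given in the sources used here. DESeq2 is also named as a tool, per the labels, with no design formula.

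Each file lists 5224 transcripts, 1 per locus. Of these loci 5182 matched RefSeq's annotation of the Arabidopsis genome by locus name and 42 did not. That annotation served for names, RNA classes and neighbouring genes only; for 94.2% of matched loci its spliced length equals the length in the files. Estimated counts were rounded, and 1.28% to 2.01% of values per library were fractional. Libraries held 474436 to 1575523 reads on these loci and 1262 to 1475 loci with reads. Within groups, pairs of replicates had log2 CPM correlations of 0.893 to 0.951 and chi-square per degree of freedom of 6.98 to 352 over 20 pairs, so spread exceeded counting error in all of them. Loci with few reads are given as a ratio with a 95% counting interval, or, where a group had 0 reads, as a lower bound against a floor of 3 reads over the group.

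Groups follow the labels. The replicates are numbered 1, 3 and 4; the labels do not say that they came from separate cultures, so p-values measure only the spread between these samples. The names of 2 sequencing files give another group than the label: the library labelled Ws DZ SCOOP12 replicate 3 is named as proscoop12 DZ control, and the library labelled proscoop12 DZ control replicate 3 as Ws DZ SCOOP12. The labels were kept, and both libraries were left out or exchanged as alternatives. File names also place replicates 1 and 3 (14 libraries) and replicate 4 (8 libraries) in different sequencing runs.

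All 22 libraries were fitted together with 8 group means in edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM normalization, filterByExpr (minimum count 10, minimum total 15), which kept 844 loci, and the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg within each comparison, and loci passed at an adjusted p under 0.05. The common dispersion was 0.133 and the median prior degrees of freedom 6.51. Standard errors (SE) are the absolute log2 fold change over the square root of F. By chance 42.2 of 844 loci have an unadjusted p under 0.05. Loci were named by a rule set before the files were opened: up to 10 each way with the largest change among those that passed, with a mean of at least 1 CPM and groups that do not overlap, up to 5 each way in interactions, and the 3 smallest p where fewer than 3 passed. AT5G00585 in the interactions with SCOOP12 and in zone in Ws, and AT1G06963 in DZ, were added after their values were seen; these 2 loci were at first added in all 14 comparisons and then limited to these 4. PROSCOOP12, MIK2, BAK1, RBOHD and the 19 gene lists were also to be followed, and none of them has a value.

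A further 4 comparisons were chosen after the data had been seen: SCOOP12 averaged over the genotypes in each zone, its difference between zones, and the zones in proscoop12. RNA classes of at least 5 tested loci were tested with camera (preset correlation 0.01, and an estimated correlation as the alternative), also chosen afterwards. Of the 844 loci, 461 overlap a coding exon on the opposite strand, 94 on the same strand, and 115 share at least 100 nt (or 90% of the shorter locus) at 95% identity or more with a coding transcript (blastn 2.17.0); their values are uncertain because reads of the coding gene can count there.

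After group means were removed, replicates of the same number were compared by correlation over the 844 loci. With 3 pairs each, these correlations were 0.138 to 0.316 for genotype in MEZ, 0.126 to 0.358 and 0.255 to 0.450 for SCOOP12 in proscoop12 MEZ and DZ, and 0.109 to 0.325 for the zones in proscoop12, against at most 0.0619 for other pairs. The numbers were therefore taken to pair the samples in these comparisons. For them, a fit with the replicate number as a block is given where a call changed or a count moved more than 1.5 times. It is also given for AT1G06963 in MEZ. The other comparisons have 2 same-number pairs or are interactions. Their blocked values are given with the alternatives, and for SCOOP12 in Ws MEZ also beside the result. Ws MEZ SCOOP12 and Ws DZ control have no replicate 1. Without the block, SCOOP12 in Ws, zone in Ws and genotype in DZ therefore set replicates 3 and 4 against replicates 1, 3 and 4. The pairing comes from the data and not from the labels. The pipeline was tested on simulated data with 200 changed loci, where 2.24% to 5.88% of calls were false. Changing 200 loci at once eases the Benjamini-Hochberg threshold, so recovery would be lower where few loci change. Beyond the changed loci, the simulation held no differences between groups or replicate numbers.

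Alternatives were DESeq2 1.42.0, RLE normalization, no filter, a stricter filter, the replicate block, only libraries of the zone compared, leaving out or exchanging the 2 libraries, only replicates 1 and 3, and leaving out each library in turn. Fits without ribosomal loci and with only replicates 3 and 4, with or without the block, were added after the data had been seen. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.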

Results

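RNA was sequenced from roots of 11-day-old Arabidopsis thaliana plants, separately for the meristematic-elongation zone (MEZ) and the differentiation zone (DZ). Wild-type plants of the Ws accession were set beside the proscoop12 mutant, which is affected in PROSCOOP12, the gene that encodes the precursor of the secreted peptide SCOOP12. Plants of both genotypes received water (control) or 100 nM SCOOP12. The 22 libraries fell into 8 groups: 3 libraries in each of 6 groups and 2 in each of Ws MEZ with SCOOP12 and Ws DZ control. The values analysed here cover 5224 transcripts, 1 per locus, of which 5175 are annotated as non-coding RNA, 7 as pseudogenes and 0 as protein-coding. Protein-coding transcripts were not analysed here. PROSCOOP12 (AT5G44585), MIK2, BAK1 and RBOHD therefore have no value, and 0 of the 404 genes in 19 lists of peroxidase, immunity, hormone, cell wall, cell type and stress genes could be followed. The targeted gene accordingly gives no check of the genotype labels.

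Estimated reads on these transcripts ranged from 474436 to 1575523 per library. Ribosomal RNA and the stretches of ribosomal DNA took 79.8% to 90.3% of them, which left 75634 to 161833 reads per library on all other loci. Nuclear rRNA contributed a mean of 38.1% of reads, organellar rRNA 26.5%, and long non-coding RNAs (lncRNAs) 5.16%. Organellar rRNA took 17.2% to 21.9% of reads in every MEZ library and 36.1% to 43.9% in the DZ controls. In DZ with SCOOP12 it took 46.9% and 38.2% in replicate 1 of Ws and of proscoop12, and 19.7% to 25.2% in replicates 3 and 4. Of the 2599 loci with reads in any library, 844 passed the expression filter and were tested: 499 lncRNAs, 132 miscellaneous RNAs (misc_RNA), 106 other non-coding RNAs (ncRNA), 42 snoRNAs, 24 snRNAs, 17 miRNA precursors, 14 antisense RNAs and 10 rRNA or tRNA loci. Levels are given as reads per 1000000 reads on the 844 tested loci, with library sizes scaled by TMM (CPM). Ratios and bounds for loci with few reads use the same scaled sizes.

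**Figure D1:**
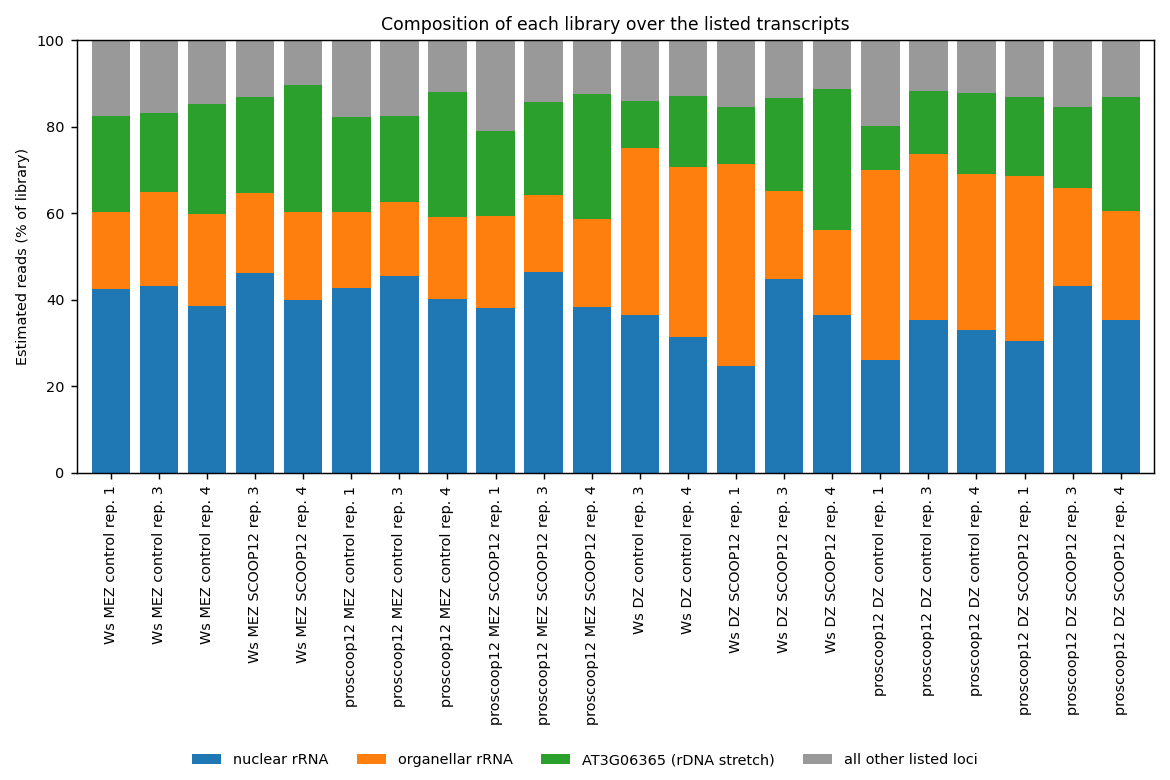
Share of estimated reads (%, linear axis) on nuclear rRNA, organellar rRNA, the ribosomal DNA locus AT3G06365 and all other listed loci. There is 1 stacked bar for each of the 22 libraries. Percentages are of the reads on the listed transcripts, which hold no protein-coding ones, and not of all reads sequenced. Organellar rRNA took 36.1% to 43.9% of reads in the DZ controls and 17.2% to 21.9% in the MEZ libraries.

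The comparison of proscoop12 with Ws without added peptide asked which loci differ with genotype alone. In MEZ, AT1G06963, an 826 nt lncRNA that overlaps no coding exon, stood at 79.5 ± 17.0 CPM in proscoop12 and 17.8 ± 6.31 CPM in Ws (SD, n = 3 each). It rose by a log2 fold change of 2.15 (SE 0.43) in proscoop12 and was higher in all 3 mutant libraries than in all 3 wild-type libraries, with an adjusted p of 0.0489 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In DZ its levels were 37.2 ± 7.53 CPM in proscoop12 (SD, n = 3) and 14.8 ± 2.998 CPM in Ws (SD, n = 2), and this difference did not pass (log2 fold change 1.33, SE 0.51, edgeR adjusted p 0.974). With SCOOP12, its levels were 85.9 ± 20.7 against 11.4 ± 5.40 CPM in MEZ and 45.9 ± 6.24 against 9.27 ± 7.09 CPM in DZ. The 12 proscoop12 libraries lay between 30.4 and 103 CPM and the 10 Ws libraries between 1.24 and 25.1 CPM. The DZ values and those with SCOOP12 were chosen for mention after they were seen. In MEZ with the replicate number as a block, AT1G06963 was the only locus to pass (log2 fold change 2.12, edgeR adjusted p 0.00868). Without the block it was also the only locus of 844 that passed in MEZ, where 14 had an unadjusted p under 0.05 and DESeq2 also called 1. AT5G05875 (log2 fold change 1.29, SE 0.38) and AT1G09835 (-2.06, SE 0.68, with 3 reads in all proscoop12 MEZ controls) had the next smallest p and did not pass (edgeR adjusted p 1.0 for both). The call for AT1G06963 was lost when any of the 6 MEZ control libraries was left out, at log2 fold changes of 1.97 to 2.48, and under 10 of 19 alternative settings in all (adjusted p from 0.000167 to 1).

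**Figure D2:**
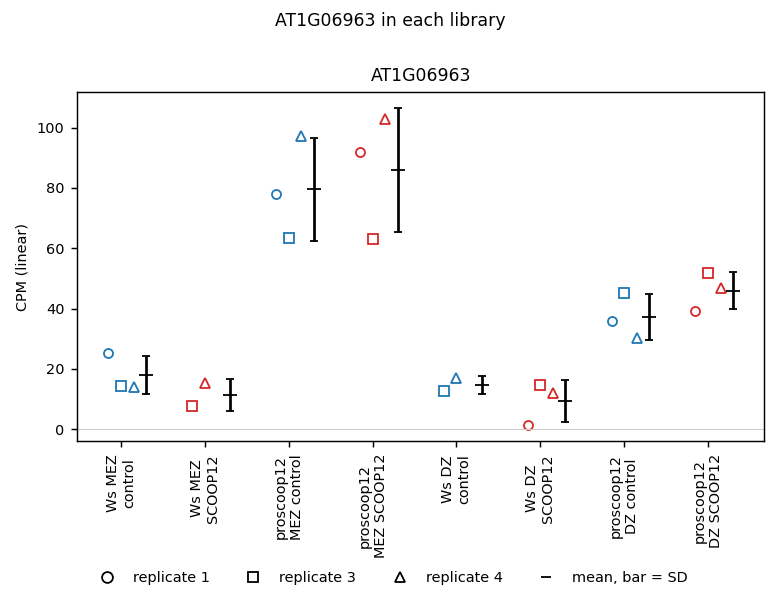
Level of AT1G06963 (CPM, linear axis) in each library of the 8 groups, with symbols for the replicate number, blue for control and red for SCOOP12, and bars for the mean ± SD of 2 or 3 libraries. The 12 proscoop12 libraries sit between 30.4 and 103 CPM, above the 10 Ws libraries at 1.24 to 25.1 CPM.

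In DZ, 0 of 844 loci passed between proscoop12 and Ws under edgeR and 0 under DESeq2, with 32 at an unadjusted p under 0.05. The smallest p belonged to AT4G03275, at 32.0 ± 9.73 CPM in proscoop12 (SD, n = 3) and 71.9 ± 0.696 CPM in Ws (SD, n = 2), a log2 fold change of -1.18 (SE 0.37, edgeR adjusted p 0.974). AT4G02795 (-1.07, SE 0.35) and AT1G27921 (-2.07, SE 0.68), which lies opposite exons of the microtubule-associated protein gene MAP65-8, followed with the same adjusted p. With simulated changes of 4-fold in this comparison, 61.4% of changed loci were recovered among 844, and 18.7% of those with a 2-fold change.

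SCOOP12 was added to Ws to ask which loci respond to the peptide in wild-type roots. In MEZ, AT5G00585 rose from 91.2 ± 15.8 CPM (SD, n = 3) to 436 ± 59.9 CPM (SD, n = 2), a log2 fold change of 2.25 (SE 0.31, edgeR adjusted p 0.000306). AT5G00585 is a misc_RNA of 1622 nt on chromosome 5, in the stretch of genes that includes PROSCOOP12: counted from AT5G44562 it is gene 6 and PROSCOOP12 gene 18 of the 20 genes considered. It overlaps AT5G06585, a lncRNA on the same strand with 0 reads in all libraries, and no coding exon. AT2G00870, a misc_RNA with 69.1% of its length opposite exons of AT2G34930, rose from 47.5 ± 3.65 to 125 ± 22.5 CPM (SD, n = 3 and 2), a log2 fold change of 1.39 (SE 0.27, edgeR adjusted p 0.0198). Both were higher in both treated libraries than in all 3 controls, which the rule for naming loci requires. AT4G02845, a misc_RNA, was at 135 ± 36.0 CPM in control and 402 ± 69.8 CPM with SCOOP12 but did not pass (log2 fold change 1.57, SE 0.36, edgeR adjusted p 0.0890). With the replicate number as a block AT4G02845 passed (log2 fold change 1.35, edgeR adjusted p 0.000157). Without the block, AT5G00585 and AT2G00870 were the 2 loci of 844 that passed, beside 8 under DESeq2 and 10 with the block. AT2G00870 lost its call when any of the 5 libraries was left out (log2 fold changes of at most 1.57), which left AT5G00585 as the 1 locus passing each time.

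In Ws DZ, AT5G00585 rose from 32.4 ± 16.6 CPM (SD, n = 2) to 145 ± 47.0 CPM (SD, n = 3), a log2 fold change of 2.17 (SE 0.35, edgeR adjusted p 0.00323). AT3G00880, a misc_RNA, fell from 1670 ± 423 to 493 ± 258 CPM, a log2 fold change of -1.76 (SE 0.33, edgeR adjusted p 0.00751). AT1G31935, an ncRNA of 529 nt, fell from 2704 ± 848 to 864 ± 165 CPM, a log2 fold change of -1.65 (SE 0.28, edgeR adjusted p 0.00379). Neither of the loci that fell overlaps a coding exon, and for all of these 3 loci the 3 treated libraries lay on the same side of both controls. The organellar rRNA share was 38.5% and 39.3% in these controls, 20.3% and 19.7% in SCOOP12 replicates 3 and 4, and 46.9% in SCOOP12 replicate 1, which also stood apart from replicates 3 and 4 (chi-square per degree of freedom 250 and 352, against 75.05 between those). These 3 were all that passed among 844, where DESeq2 called 11 and replicates 3 and 4 alone gave 7, while 0 passed with DZ libraries only, with replicates 1 and 3 alone, or with the labels exchanged between the 2 libraries whose file names disagree with them. AT5G00585 lost its call without Ws DZ control replicate 3 (log2 fold change 1.72), as did AT1G31935 (-1.29), and AT3G00880 lost it without Ws DZ control replicate 4 (-1.48) or Ws DZ SCOOP12 replicate 3 (-1.52) or 4 (-1.66), while the number passing was 1 without control replicate 3 and 6 without SCOOP12 replicate 1.

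The same treatment of proscoop12 asked which loci respond where the plant's own PROSCOOP12 is affected. In MEZ, 7 loci rose and 0 fell. AT5G00585 rose from 70.3 ± 10.2 to 369 ± 28.9 CPM (SD, n = 3 each), a log2 fold change of 2.39 (SE 0.29, edgeR adjusted p 5.0e-05), and AT4G02845 from 111 ± 25.8 to 410.5 ± 149 CPM, a log2 fold change of 1.89 (SE 0.34, adjusted p 0.00723). AT5G06865, with 74.0% of its length opposite exons of PGIP1, a gene for an inhibitor of fungal polygalacturonases, rose from 395 ± 153 to 1246 ± 333 CPM (log2 fold change 1.66, SE 0.34). AT2G00870 (log2 fold change 1.14, SE 0.25), AT5G02895 (1.38, SE 0.30, opposite AT5G18470) and AT1G07128 (0.94, SE 0.21, opposite the telomere maintenance gene STN1) rose as well. AT1G09835, a misc_RNA, had 26 reads with SCOOP12 and 3 in the controls, a ratio of 8.70 with a 95% counting interval of 2.67 to 44.9. Adjusted p was 0.0203 for each of these last 5 loci, and each of the 7 was higher in all 3 treated libraries than in all 3 controls, as the naming rule requires. Replicates with the same number deviated together, and the fit with the replicate number as a block called 23 loci, 18 higher and 5 lower, among them all 7, where DESeq2 without the block called 12. The number passing was 1 without proscoop12 MEZ control replicate 1 or 3, and 3 without control replicate 4 or SCOOP12 replicate 1; AT5G00585 passed in each case, and AT4G02845 lost its call without control replicate 1 (log2 fold change 1.77) or 3 (1.85).

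In proscoop12 DZ, 4 loci rose and 7 fell with SCOOP12. AT3G22121, which lies wholly opposite exons of CWLP, a gene for a cell wall linker protein, rose from 2.62 ± 0.996 to 32.4 ± 13.4 CPM (SD, n = 3 each), a log2 fold change of 3.51 (SE 0.74, edgeR adjusted p 0.0201). AT5G00585 rose from 23.8 ± 2.99 to 134 ± 25.5 CPM (2.50, SE 0.31, adjusted p 3.73e-05), AT1G07937 from 9.18 ± 4.605 to 36.7 ± 16.1 CPM (2.004, SE 0.45, adjusted p 0.0282) and AT1G04425 from 123 ± 16.8 to 291.4 ± 40.1 CPM (1.24, SE 0.24, adjusted p 0.00997). AT3G00880 fell from 1718 ± 251 to 299 ± 70.2 CPM, a log2 fold change of -2.52 (SE 0.31, adjusted p 3.73e-05), and AT1G31935 from 2576 ± 210 to 725 ± 114 CPM (-1.83, SE 0.26, adjusted p 0.000226). AT4G03585 (-2.01, SE 0.46), opposite the cutin biosynthesis gene CYP86A2, and AT1G04247 (-1.41, SE 0.33), opposite KCS2, a gene of very-long-chain fatty acid elongation, also fell, as did AT1G08173 (-1.98, SE 0.43), AT4G06685 (-1.94, SE 0.47) and AT3G27884 (-1.31, SE 0.30). Adjusted p for these 5 ranged from 0.0201 to 0.0371, and at each of the 11 loci the 3 treated libraries lay on the same side of all 3 controls. The organellar rRNA share moved with this group: it was 36.1% to 43.9% in the 3 controls, 22.5% and 25.2% in SCOOP12 replicates 3 and 4, and 38.2% in SCOOP12 replicate 1. The fit with the replicate block called 50 loci, 28 higher and 22 lower, including all 11, DESeq2 called 22, the fit of replicates 3 and 4 alone 6, DZ libraries only 3, and replicates 1 and 3 alone 3. With labels exchanged between the 2 libraries whose file names disagree with them, of which proscoop12 DZ control replicate 3 is 1, 0 passed and AT5G00585 was at a log2 fold change of 0.69 (edgeR adjusted p 0.984). Without proscoop12 DZ control replicate 1 or SCOOP12 replicate 3 the number passing was 4, without SCOOP12 replicate 4 it was 5, and without control replicate 3 or SCOOP12 replicate 1 it was 6; AT5G00585, AT3G00880 and AT1G31935 passed each time, AT1G04425 lost its call only without control replicate 3, and the other 7 each lost it without at least 3 of the 6 libraries.

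**Figure D3:**
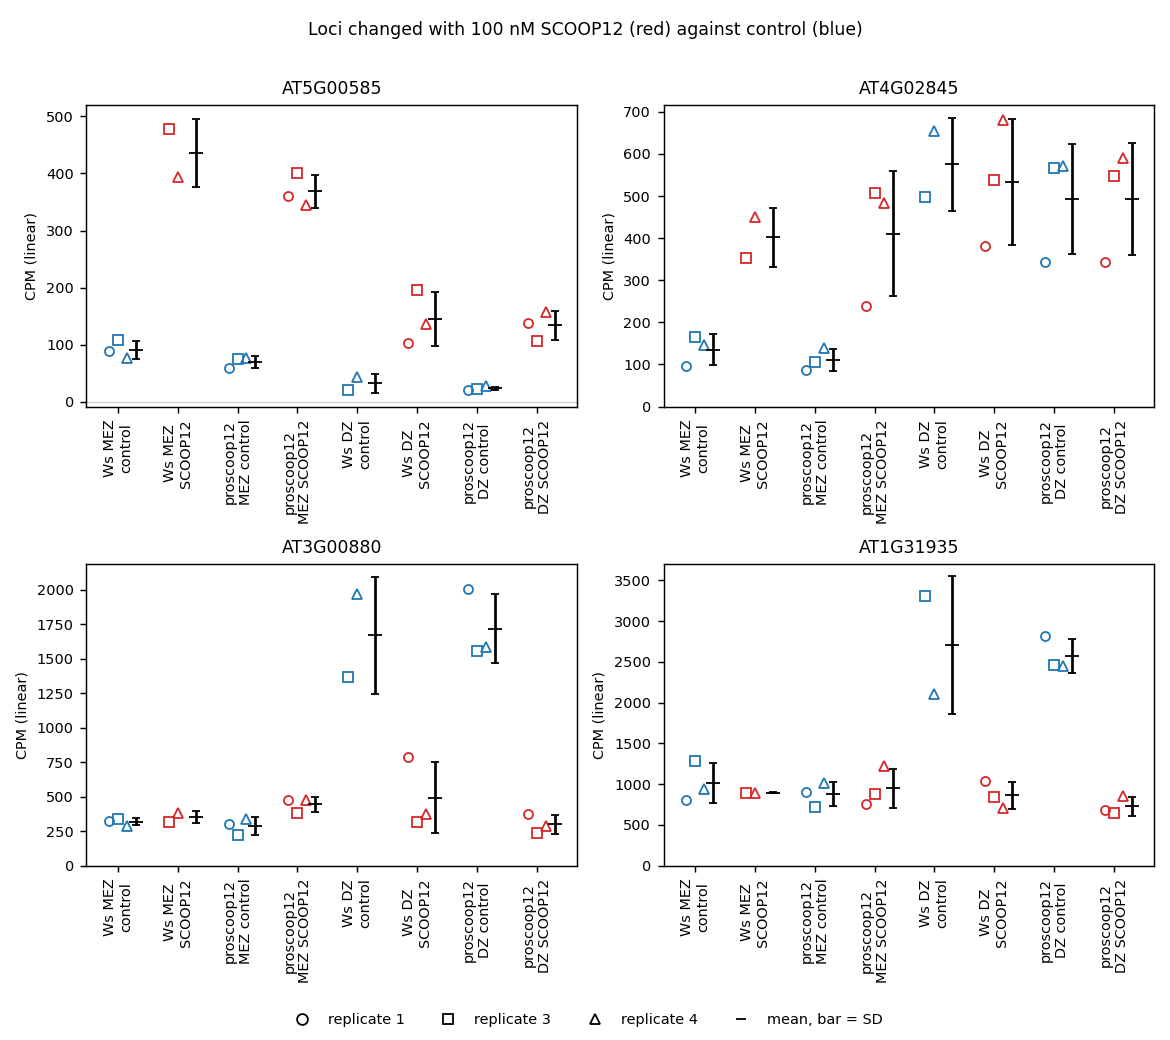
Levels of AT5G00585, AT4G02845, AT3G00880 and AT1G31935 (CPM, linear axes) in each library, with symbols for the replicate number, blue for control and red for SCOOP12, and bars for the mean ± SD of 2 or 3 libraries. AT5G00585 was higher with SCOOP12 in both zones of both genotypes, AT4G02845 stood at 111 CPM in proscoop12 MEZ controls and 410.5 CPM with SCOOP12, and AT3G00880 and AT1G31935 were lower with SCOOP12 in DZ.

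Whether the response to SCOOP12 differs between the genotypes was tested as an interaction. AT5G00585 differed by a log2 value of 0.14 (SE 0.41, edgeR adjusted p 0.9999) in MEZ and 0.33 (SE 0.44, adjusted p 0.9999) in DZ, where the sign turned to -0.32 without Ws DZ control replicate 4. In MEZ, 0 of 844 loci passed under edgeR and 0 under DESeq2, with 15 at an unadjusted p under 0.05. The smallest p were those of AT2G03875 (log2 difference -3.20, SE 0.96), a ribosomal DNA locus, AT1G09185 (-2.51, SE 0.90), which has a near-identical coding copy, and AT2G39675 (-1.57, SE 0.57), the trans-acting siRNA precursor TAS1C. In DZ, 0 loci passed under edgeR and 0 under DESeq2, with 21 at an unadjusted p under 0.05. The smallest p were those of AT3G09965 (-4.51, SE 1.39; wholly opposite scpl40) and AT3G05925 (-4.66, SE 1.45), each with 1 read in Ws DZ controls, and AT1G19968 (-2.91, SE 0.91). Adjusted p was 0.9999 for all 6. In simulations of the MEZ interaction 56.4% of 4-fold changes were recovered among 844 loci, and 34.7% in DZ. Across the 844 loci, which are not independent replicates, log2 fold changes with SCOOP12 in Ws and in proscoop12 had a correlation r of 0.37 in MEZ and 0.35 in DZ, and all 2 and all 3 loci called in Ws were also called in proscoop12 in the same direction.

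The zones were compared in control Ws to show which loci separate MEZ from DZ. Of 844 loci, 77 were higher and 78 lower in DZ, and DESeq2 also called 155. AT3G04615, a lncRNA with 95.9% of its length opposite AT3G24020, fell from 474 ± 94.9 CPM in MEZ (SD, n = 3) to 15.2 ± 14.2 CPM in DZ (SD, n = 2), a log2 fold change of -4.92 (SE 0.66, edgeR adjusted p 8.16e-05). AT1G19968, an ncRNA with no coding overlap, fell from 170.7 ± 19.5 to 4.10 ± 3.96 CPM (-5.29, SE 0.71, adjusted p 8.16e-05). AT4G03585, opposite CYP86A2, rose from 38.8 ± 11.1 to 257 ± 75.6 CPM (2.72, SE 0.51, adjusted p 0.00137), and AT4G09215 from 13.6 ± 4.54 to 112 ± 106 CPM (3.02, SE 0.67, adjusted p 0.00383). AT3G21781, opposite the abscisic acid glucosyltransferase gene UGT71B6 (2.60, SE 0.68), AT5G09215 (2.63, SE 0.65), AT3G08375 (3.02, SE 0.86), AT1G67105 (3.13, SE 1.08) and AT1G08825 (2.63, SE 0.85), which has a near-identical coding copy, also rose. AT5G00585, chosen after its values were seen, was lower in DZ (-1.50, SE 0.34, adjusted p 0.00479). The libraries of the zones do not overlap at these loci, which the naming rule requires of all but AT5G00585. Of the 155 loci, 68 overlap a coding exon on the opposite strand, 12 on the same strand, and 16 have a near-identical coding copy.

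Several of the loci with the largest fitted changes had few reads in one zone. AT5G09735 had 51 reads in the Ws MEZ controls and 0 in the DZ controls, which makes it at least 12.2-fold lower in DZ against a floor of 3 reads over the group. On the same floor AT2G08695 was at least 8.87-fold, AT1G07847 at least 6.48-fold and AT4G04015 at least 4.56-fold lower, AT1G07933 at least 2.64-fold lower, and AT4G10507 at least 4.63-fold higher. AT3G09965 was lower in DZ by a ratio of 53.2 on 74 reads against 1 (95% counting interval 9.26 to 2131), AT1G24068 by 26.6 on 37 against 1 (4.49 to 1079) and AT5G09745 by 23.5 on 98 against 3 (7.81 to 116). AT1G08763 was higher in DZ by a ratio of 52.1 on 75 reads against 2 (13.9 to 438) and AT3G08115 by 20.8 on 30 against 2 (5.29 to 180.0). All of these passed (edgeR adjusted p 0.00137 to 0.0305); the intervals and floors cover counting error only. Without Ws DZ control replicate 4 the number of loci passing was 51, without Ws DZ control replicate 3 it was 94, and without Ws MEZ control replicate 1 it was 95. Among the loci named for this comparison, AT3G08115, AT4G03585, AT3G09965, AT1G19968 and AT3G04615 passed whichever of the 5 libraries was left out, AT1G08763 moved to a log2 fold change of 2.53 and AT4G09215 to 1.44 without Ws DZ control replicate 4, both without passing (AT1G08763 also failed to pass without Ws MEZ control replicate 1), AT5G00585 lost its call without Ws DZ control replicate 3 (-1.04), and the others lost theirs without at least 1 library.

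Whether the difference between zones depends on genotype was tested as an interaction in control roots. The smallest p were those of AT1G09835 (log2 difference 3.004, SE 0.85), MIR842 (AT1G61224; -1.80, SE 0.52) and TAS1C (AT2G39675; -1.92, SE 0.59), with edgeR adjusted p of 0.995, 0.995 and 0.9999. In the proscoop12 controls AT1G09835 stood at 1.104 ± 1.04 CPM in MEZ and 20.0 ± 3.97 CPM in DZ (SD, n = 3 each), and in the Ws controls at 5.26 ± 2.04 (n = 3) and 10.4 ± 0.0317 CPM (n = 2). Of 844 loci, 0 passed under edgeR and 0 under DESeq2, and 27 had an unadjusted p under 0.05. Simulated 4-fold changes in this interaction were recovered for 45.7% of changed loci among 844.

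A further comparison, chosen after the data had been seen, asked whether the zones differ as much with SCOOP12 as without it. For the 155 loci that separated the zones in control Ws, the zone differences in proscoop12 shrank with SCOOP12 to 0.591 of their control size (95% bootstrap interval over loci 0.513 to 0.681), and 132 of the 155 were smaller. AT3G00880, AT4G03585 and AT4G02845 were among the loci whose higher level in DZ than in MEZ was reduced or lost. AT3G00880 stood at 1718 CPM in proscoop12 DZ and 287 CPM in MEZ without SCOOP12, and at 299 and 446 CPM with it. At AT4G02845 in proscoop12 the zone difference went from a log2 value of 2.15 to 0.27. Its level in MEZ rose with SCOOP12 (log2 fold change 1.89). For the 167 loci that separated the zones in control proscoop12, the ratio measured in Ws was 0.410 (0.346 to 0.476), with 151 smaller. The bootstrap treats loci as independent, which they are not.

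**Figure D4:**
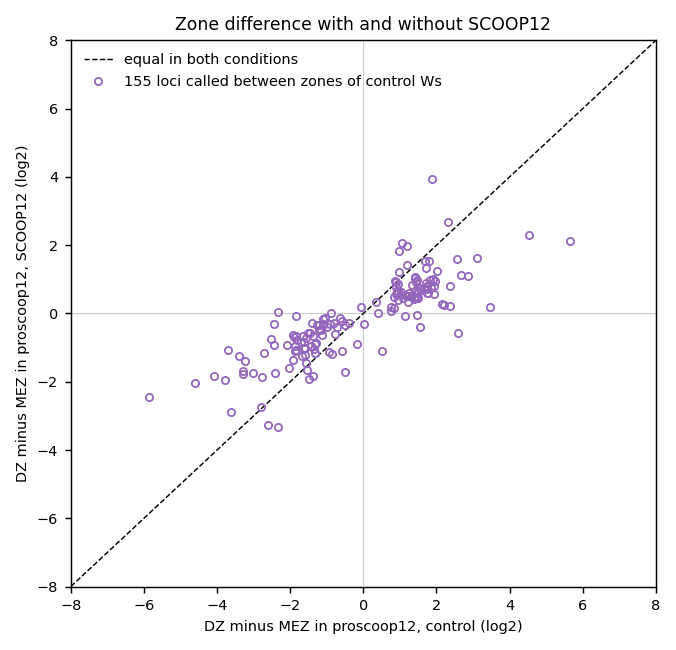
Difference between DZ and MEZ (log2 fold change) in proscoop12 for the 155 loci that separated the zones in control Ws, without SCOOP12 on the horizontal axis and with it on the vertical axis, 1 point per locus, 3 libraries per group. The dashed line marks equal differences; 132 of the 155 points have a smaller difference with SCOOP12.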

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

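The tests of smaller zone differences named here were written down before they were run, but after correlations between zone and SCOOP12 changes had been seen, and the zone by SCOOP12 comparison itself was chosen after the data had been seen. A test of the difference between zones in the response to SCOOP12, averaged over the genotypes, called 22 of 844 loci, 13 higher and 9 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The response was higher in DZ than in MEZ for AT5G09295 (log2 difference 3.58, with 1 read in proscoop12 DZ controls), AT3G00260 (3.08), AT3G04615 (2.79, opposite AT3G24020), AT4G22233 (2.45, opposite AT4G22235) and AT4G06135 (2.40, opposite AT4G13580). It was lower in DZ for AT4G03585 (-2.78, opposite CYP86A2), AT3G00880 (-2.53), AT3G52748 (-2.14), AT1G08803 (-1.79, opposite TPX2) and AT4G02845 (-1.78). The block on replicate number called 73 loci, and without Ws DZ control replicate 4 the number was 5.

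The zones differed less in the libraries with SCOOP12, and the organellar rRNA share moved with this in part: in DZ with SCOOP12 it was 19.7% to 25.2% in replicates 3 and 4, near the 17.2% to 21.9% of MEZ, but 46.9% and 38.2% in replicate 1, near or above the 36.1% to 43.9% of the DZ controls. Without ribosomal loci 24 loci passed. Dropping them moved the median log2 change over all loci only from 0.042 to -0.00897. This fit could therefore hardly differ, and it does not test ribosomal RNA taking the reads as a cause. With replicates 3 and 4 alone the ratio of zone differences in proscoop12 was 0.468 (95% bootstrap interval 0.397 to 0.537). That ratio argues against replicate 1 as the cause, although without replicate 4 the ratio was 0.811 (0.545 to 1.08) over 11 loci. Mixed zones at dissection would move both zones towards each other at loci of both kinds, and that is what was measured in proscoop12. Each fraction is the change with SCOOP12 in proscoop12 over the zone difference in Ws controls. The 95% bootstrap intervals resample loci and leave out the spread between libraries. In MEZ, loci higher in MEZ moved by a median 0.279 of the zone difference (0.198 to 0.334) and loci higher in DZ by 0.163 (0.139 to 0.220). In DZ, the loci higher in DZ moved by 0.129 (0.0245 to 0.317) and those higher in MEZ by 0.139 (0.0894 to 0.192). Ws was not measured in this way. Mixing of tissue and a response to SCOOP12 that makes the zones more alike therefore both remain possible explanations. Mixing cannot produce the level of AT5G00585 in MEZ with SCOOP12, 369 CPM in proscoop12 against 70.3 and 23.8 CPM in the MEZ and DZ controls.

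Tests of whole RNA classes, with a preset correlation, differed between groups for ncRNA in the genotype by SCOOP12 interaction in MEZ (lower, adjusted p 0.00635), snRNA in that interaction in DZ (lower, adjusted p 0.00287), and misc_RNA (lower, adjusted p 0.0116), ncRNA (lower, adjusted p 0.0116) and snRNA (higher, adjusted p 0.000512) in the genotype by zone interaction, by limma's camera with Benjamini-Hochberg adjustment. With an estimated correlation 0 classes passed in any comparison, the adjusted p of these 5 were 0.429, 0.912, 0.326, 0.366 and 0.326, and 0 single loci passed in these interactions. Both snRNA results use the proscoop12 DZ controls, so they are not independent. With the preset correlation camera also called snRNA for genotype in DZ (higher, adjusted p 0.00708) and SCOOP12 in proscoop12 DZ (lower, adjusted p 0.000673). Those comparisons use the same controls, and in SCOOP12 in Ws DZ, which does not, snRNA did not pass (adjusted p 0.801). Over 14 comparisons 16 class results passed with that correlation.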

How the results depend on the processing

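Counts of loci passing are given for each setting, beside those of the fit in the report; unless a setting has fewer libraries or loci by construction, the cause was not tested. Genotype in MEZ (1 in the report) gave 0 with the 2 libraries left out, 0 with their labels exchanged, 0 with replicates 1 and 3 alone and 0 without ribosomal loci. Genotype in DZ (0) gave 4 with no filter and 1 with the block in replicates 3 and 4. SCOOP12 in Ws MEZ (2) gave 8 with DESeq2, 11 with no filter, 1 with the stricter filter, 10 with the block, 1 with MEZ libraries only, 0 with labels exchanged, 11 with the block and the 2 libraries left out, 0 with replicates 1 and 3 and 14 with the block in replicates 3 and 4. SCOOP12 in Ws DZ (3) gave 11 with DESeq2, 11 with no filter, 11 with the block, 0 with DZ libraries only, 0 with labels exchanged, 0 with replicates 1 and 3, 7 with replicates 3 and 4 and 33 with the block in these. SCOOP12 in proscoop12 MEZ (7) gave 12 with DESeq2, 19 with no filter, 3 with the stricter filter, 23 with the block, 3 with MEZ libraries only, 21 with the block and the 2 libraries left out, 1 with replicates 1 and 3 and 32 with the block in replicates 3 and 4. SCOOP12 in proscoop12 DZ (11) gave 22 with DESeq2, 22 with no filter, 50 with the block, 3 with DZ libraries only, 0 with labels exchanged, 23 with the block and the 2 libraries left out, 3 with replicates 1 and 3, 6 with replicates 3 and 4 and 34 with the block in these. Genotype by SCOOP12 in MEZ (0) and genotype by zone (0) each gave 1 with no filter. Zone in Ws (155) gave 11 with replicates 1 and 3. SCOOP12 over both genotypes in MEZ (24) gave 39 with no filter, 63 with the block, 52 with the block and the 2 libraries left out, 2 with replicates 1 and 3, 38 with replicates 3 and 4 and 72 with the block in these. The same in DZ (34) gave 16 with the stricter filter, 84 with the block, 11 with DZ libraries only, 14 with the 2 libraries left out, 0 with labels exchanged, 69 with the block and the 2 left out, 4 with replicates 1 and 3 and 89 with the block in replicates 3 and 4. Zone by SCOOP12 (22) gave 36 with DESeq2, 11 with the stricter filter, 73 with the block, 11 with the 2 libraries left out, 4 with labels exchanged, 41 with the block and the 2 left out, 0 with replicates 1 and 3 and 55 with the block in replicates 3 and 4. Zone in proscoop12 (167) gave 268 with the block and 74 with replicates 1 and 3. AT5G00585 in the genotype by SCOOP12 interaction in DZ turned from 0.33 to -0.75 with labels exchanged, -0.42 with replicates 1 and 3 and ranged from -0.32 without Ws DZ control replicate 4 to 0.77 without Ws DZ control replicate 3. Leaving out each library in turn gave 0 to 0 loci for genotype in MEZ, 1 to 1 and 1 to 6 for SCOOP12 in Ws MEZ and DZ, 1 to 7 and 4 to 10 in proscoop12 MEZ and DZ, 51 to 145 for zone in Ws, 11 to 31 and 9 to 37 for SCOOP12 over both genotypes in MEZ and DZ, 5 to 25 for zone by SCOOP12, at least 116 for zone in proscoop12, and 0 to 0 for genotype in DZ and the interactions. Where this left 1 library in a group, that library was assumed to vary like the other groups. Of 1103 values of named loci with a library left out, 854 stayed on the same side of the threshold, passed or not, 1 reversed and the rest no longer passed; of 1560 under the other settings, 1310 stayed on the same side, 241 no longer passed, 7 newly passed and 2 reversed. The log2 fold change of AT5G00585 with SCOOP12 ranged from 2.11 to 2.39 in Ws MEZ, 1.44 to 2.82 in Ws DZ, 2.29 to 2.55 in proscoop12 MEZ and 0.69 to 2.64 in proscoop12 DZ, and it did not pass under 2 of 18, 4 of 18, 1 of 19 and 1 of 19 settings. With RLE normalization all 126 named values stayed on the same side, and with the block 125 did, with AT4G02845 in Ws MEZ newly passing and no other call of a named locus changed. The block took the adjusted p of the 5 class results in the interactions to 0.371 (ncRNA, genotype by SCOOP12 in MEZ), 0.00017 (snRNA, in DZ), 0.0537 (misc_RNA), 0.326 (ncRNA) and 2.09e-05 (snRNA, these 3 in genotype by zone). In comparisons with 2 same-number pairs these correlated at 0.283 to 0.382 for genotype in DZ, 0.160 to 0.170 and 0.246 to 0.297 for SCOOP12 in Ws MEZ and DZ and 0.151 to 0.353 for zone in Ws. The gene list tests gave no value. With 75634 to 161833 reads outside ribosomal loci, simulated 2-fold changes were recovered for 5.56% to 47.6% of loci, depending on the comparison.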

Other observations

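The comparisons in this paragraph were chosen after the data had been seen. Averaged over the genotypes, SCOOP12 in MEZ was followed by 19 loci that rose and 5 that fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), against 63 in all with the replicate block, 11 without Ws MEZ SCOOP12 replicate 3, 13 without Ws MEZ SCOOP12 replicate 4 and 2 with replicates 1 and 3 alone. AT5G00585 rose by a log2 fold change of 2.32 (SE 0.21, adjusted p 3.79e-07), AT3G52748 by 1.95 (SE 0.41, adjusted p 0.00648), AT4G02845 by 1.73 (SE 0.25, adjusted p 0.000239), and AT5G44562, opposite VPS2.2, by 1.36 (SE 0.31, adjusted p 0.0129). The stretch of chromosome 5 described for AT5G00585 and PROSCOOP12 was set to start at AT5G44562, so the place of AT5G44562 in it is not a result. AT4G22233 fell by 2.36 (SE 0.48), AT3G05905 by 1.13 (SE 0.23) and AT1G76878 by 0.85 (SE 0.21), each opposite a coding gene. In DZ 19 rose and 15 fell, against 84 in all with the block, 11 with DZ libraries only, 14 with the 2 libraries whose file names disagree with their labels left out and 0 with their labels exchanged. The count was 9 without Ws DZ control replicate 4, 21 without Ws DZ SCOOP12 replicate 4, 22 without proscoop12 DZ SCOOP12 replicate 1 and 4 with replicates 1 and 3 alone. AT3G22121 rose by 2.99 (SE 0.53), AT3G06962 by 2.37 (SE 0.49), AT5G00585 by 2.33 (SE 0.23) and AT1G07937 by 1.89 (SE 0.34), and AT3G00880 fell by 2.14 (SE 0.23), AT1G31935 by 1.74 (SE 0.19), AT1G08173 by 1.58 (SE 0.31) and the mitochondrial rRNA ATMG01390 by 1.08 (SE 0.25). Among 100 splits of the libraries, the labelled split gave 24 loci in MEZ, 34 in DZ and 22 for their difference, the highest other splits gave 12, 13 and 12, and in each case 1 of 100 splits, the labelled split itself, reached the count. The splits were drawn within genotype and zone and ignored the replicate number, although same-number replicates deviate together.

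In control proscoop12, 84 loci were higher and 83 lower in DZ than in MEZ (268 with the replicate block), and 113 of these were also among the 155 of Ws, all in the same direction, where 7.66 shared higher and 7.67 shared lower loci are expected by chance. AT4G03585 was higher by a log2 fold change of 3.46 (SE 0.50, edgeR adjusted p 0.00011), AT3G00880 by 2.58 (SE 0.31, adjusted p 2.67e-05) and AT4G06790 by 2.87 (SE 0.45, adjusted p 0.000218), and AT3G22121 was lower by 4.09 (SE 0.73, adjusted p 0.000515) and so was AT4G06135 (-3.40, SE 0.54, adjusted p 0.00022). AT1G08487 had 52 reads in DZ and 0 in MEZ, at least 20.3-fold higher. Splits of 3 against 3 libraries are too few to test a count: the labelled split gave 1, 7, 11 and 167 loci for genotype in MEZ, SCOOP12 in proscoop12 MEZ and DZ and the zones in proscoop12, and the highest other of 10 splits gave 0 in each.

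For AT5G00585 the tests without ribosomal loci and over same-number pairs were chosen after its rise had been seen, and the search for copies before. It has 0 near-identical coding transcripts, and its 1 near-identical listed locus, AT5G06585, which lies within it, had 0 reads. Its lowest of 4 log2 fold changes without ribosomal loci was 2.13. It was higher with SCOOP12 in 10 of 10 same-number pairs (log2 ratio 1.61 to 3.22), but the naming rule already requires this, so the pairs test nothing. Dropping ribosomal loci moved the median log2 change over all loci at most from 0.050 to -0.0055 in these 4 comparisons (SCOOP12 in proscoop12 DZ). That fit could therefore hardly differ, and it does not test ribosomal RNA as a cause of the rise. The search for copies argues against reads shared with near-identical coding transcripts, and a response to the peptide remains a candidate explanation. Of the 2 libraries whose file names disagree with their labels, the library labelled Ws DZ SCOOP12 replicate 3 had 196 CPM of AT5G00585 and 20.3% organellar rRNA, and the library labelled proscoop12 DZ control replicate 3 had 22.6 CPM and 38.5%. AT1G06963, whose levels differ by genotype label, was at 14.7 CPM in the library labelled Ws DZ SCOOP12 replicate 3 and 45.3 CPM in the library labelled proscoop12 DZ control replicate 3, where the other DZ libraries of Ws lay between 1.24 and 16.9 CPM and those of proscoop12 between 30.4 and 51.6 CPM. No label exchange was weighed as an explanation here: its prediction was removed before its test was run.

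The strand test was written down before it was run, but after the shares of 41.9% and 5.24% had been seen for lncRNA loci with at least 50% of their length opposite a coding exon and for others. Of lncRNA loci with 90% or more of their length opposite a coding exon, 39.9% of 547 reached the test, against 10.6% of 462 loci with some but under 50% opposite, a ratio of 3.76, and 4.21% of 2160 loci with none, at median lengths of 360, 373.5 and 306 nt. This nearly repeats the split that prompted it, so it adds little. Reads of the coding gene counted on the opposite locus and antisense transcription beside expressed genes would both give this pattern, and they were not separated, since the strand that was counted is not given in the sources used here.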
